A study of Homo sapiens with 6 samples.

How the data were processed

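Single-cell RNA sequencing was read from 6 libraries of 3 human breast cancer lines, with 2 libraries each of MCF7, MCF7M1 and MCF7TR. MCF7 is an established oestrogen receptor-positive line from breast cancer, and the series sets it beside MCF7M1 and MCF7TR as a model of drug-tolerant cells. The labels describe all 6 samples as untreated. They name no drug, do not expand M1 or TR, and do not say whether these lines were made from this MCF7 stock. Cells were captured on a 10x Genomics Chromium instrument, per the labels' protocols.

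The deposited values were raw UMI counts per gene and cell barcode, written by Cell Ranger per the file headers. The headers give version 4.0.0 for both MCF7 and both MCF7TR libraries and version 5.0.0 for both MCF7M1 libraries, so the version cannot be separated from the MCF7M1 line by design. Per the submitters' processing notes, the genome build was hg19. Of the 36601 feature IDs in each library, 34616 (94.6%) were found in GENCODE 29, an annotation of a later build. No coordinates are therefore given, and GENCODE 29 was used only for the order of genes along chromosomes and for transcript GC content and length. Gene symbols are those paired with the IDs in the files. The barcodes had been called as cells before deposit, and none held fewer than 500 UMIs. Their numbers, 6172, 10156 and 6097 for MCF7, MCF7M1 and MCF7TR, equal the cell numbers stated for the series, 22425 in all.

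Cells are not replicates, so counts were summed over all deposited barcodes of each library. Library totals were 100542384 and 94994779 UMIs for MCF7, 98217911 and 99561839 for MCF7M1, and 110035737 and 105019248 for MCF7TR. Median UMIs per barcode were 26199 and 28199, 16667 and 16652, and 31834.5 and 37577 in the same order. Genes were tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment. All 6 libraries entered 1 fit, which left 3 residual degrees of freedom. Genes were counted at an adjusted p under 0.05, and again with a log2 fold change of at least 1 in size. CPM were computed on TMM-scaled library sizes and are given as mean ± SD of 2 libraries. Where a line had no UMI of a gene, the fold is a lower bound against 3 counts over both libraries of that line. Where it had 1 to 3, the fold is given with its 95% counting interval.

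Counts were also simulated from the mean MCF7 profile at the size of each library, with a dispersion common to all genes. Of 17924 genes tested, 200 genes expressed in MCF7 were changed in the simulated MCF7M1 libraries. The test recovered 26% of 1.2-fold changes, 94% of 1.5-fold changes and 100% of 2-fold and 4-fold changes. It made 2 false calls. Real genes differ in their spread, so these rates hold for that simpler setting only.

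Gene lists were compared with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 28 lists and 3 comparisons (84 tests). Each list was tested again with its estimated correlation. The lists covered oestrogen-induced genes, luminal and basal epithelial markers, mesenchymal markers, epithelial junctions, receptor tyrosine kinases, MAPK output, S phase, G2/M, interferon-stimulated genes, MHC class I, cholesterol and fatty acid synthesis, hypoxia with glycolysis, the respiratory chain, the unfolded protein response, p53 and NRF2 targets, drug transport and metabolism, YAP and TGF-beta output, stem-like and drug-tolerance genes, chromatin architecture, immediate early and heat shock genes, NF-kB targets, the BCL2 family, and markers of fibroblasts, leukocytes and endothelium. Lists, tests, alternatives and the rule for named genes were set before the data were examined.

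The rule named, for each comparison with MCF7, the 8 genes that rose and the 8 that fell most by fitted log2 fold change. For MCF7TR against MCF7M1 it named 5 and 5. Genes needed an adjusted p under 0.05, the same order of all libraries and at least 20 CPM in the higher line. Mitochondrially encoded, ribosomal protein, Y-linked and clone-named genes and XIST were left out. ESR1, PGR, GREB1, TFF1 and BCL2 were always named, as were up to 4 members of each list past the threshold.

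For values per cell, each barcode was thinned without replacement to 5000 UMIs, and barcodes with fewer were left out: 992 of MCF7, 3154 of MCF7M1 and 1457 of MCF7TR. Phases were called with scanpy 1.11.5 on the S phase and G2/M lists over all lines together. Shares of cells with a UMI, Fano factors (variance over mean of UMI counts) and nearest neighbours were computed at the same depth. Neighbours used 2000 variable genes, 30 principal components and 30 neighbours, with 1880 cells drawn from each library. For neighbours and clusters, only cells with at least 1000 genes and at most 20% mitochondrial UMIs were used. That filter passed 15604 of 22425 barcodes, and 15587 were left after doublet calls. The doublet caller scrublet marked 5, 0, 0, 0, 1 and 11 barcodes in the 6 libraries. That rate is too low for the caller to have worked, so doublets remain in the data. Values per library were compared with exact two-sided permutation tests, which with 2 libraries against 2 cannot give a p below 0.333.

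The labels do not say whether the 2 libraries of a line came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical. Within each line the libraries differed beyond counting noise, with a chi-square per degree of freedom of 22.9 in MCF7, 13.8 in MCF7M1 and 12.3 in MCF7TR, so none was a duplicate. The median absolute log2 difference between them, over genes of at least 20 CPM, was 0.07, 0.06 and 0.06.

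The alternatives were another scaling, DESeq2 1.42.0, other filters on low counts, the replicate number as a block, each pair of lines alone, each library left out, filtered cells, thinned cells and a test against a 2-fold change. With library sizes alone in place of TMM, an alternative chosen after the data were seen, the median of all genes moved by -0.10 on the log2 scale for MCF7TR against MCF7M1, and by less for the other comparisons. The single-cell Hi-C data of the same lines were not analysed here.

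Other packages were scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, leidenalg 0.10.2 and matplotlib 3.10.9 on Python 3.11.15. Alternatives added after the data were seen were library sizes alone, the estimated correlation on filtered cells, phases scored within each line, and the overlap of changes with another MCF7 library in each comparison.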

Results

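The 6 libraries hold single-cell transcriptomes of MCF7, MCF7M1 and MCF7TR, 2 libraries per line. Each library held between 94994779 and 110035737 UMIs over 2743 to 5091 barcodes. Depth per barcode was lowest in MCF7M1, with medians of 16667 and 16652 UMIs, against 26199 and 28199 in MCF7 and 31834.5 and 37577 in MCF7TR. Barcodes with over 20% mitochondrial UMIs made up 16.2% and 27.5% of the MCF7 libraries, 12.7% and 19.9% of the MCF7M1 libraries, and 37.7% and 27.7% of the MCF7TR libraries. Barcodes that failed the cell filter held between 2.40% and 6.44% of a library's UMIs. Across genes, which are not independent replicates, log2 CPM correlated at 0.996 to 0.997 within a line, 0.966 to 0.968 between MCF7 and MCF7M1, and 0.873 to 0.882 between MCF7TR and either of the others.

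The comparison of MCF7M1 with MCF7 asked how the transcriptome of this drug-tolerant model line differed from that of MCF7. AREG, which encodes the EGFR ligand amphiregulin, rose 118-fold, from 0.593 CPM in MCF7 to 69.9 ± 3.21 CPM in MCF7M1 (SD, n = 2). ESR1, the oestrogen receptor alpha gene, fell from 343 ± 23.1 to 134 ± 17.7 CPM, while the receptor's target genes TFF1 and PGR rose. TFF1 went from 1664 ± 75.6 to 4884 ± 346 CPM and PGR from 21.8 ± 8.32 to 48.7 ± 3.57 CPM. BCL2, which encodes an inhibitor of apoptosis, fell 5.45-fold to 8.62 ± 0.0211 CPM. NUPR1 and CHAC1, stress-induced genes, rose 18.3-fold to 261 ± 48.0 CPM and 18.7-fold to 22.0 ± 2.01 CPM.

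Among 18789 tested genes, 11892 (63.3%) changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5796 upward and 6096 downward. Of these, 3047 changed at least 2-fold, 1540 upward and 1507 downward. With library sizes alone, a scaling added after the data were seen, 6532 of 11855 changed genes were upward (55.1%), so the majority direction at any size depended on the scaling. At 2-fold 1735 of 3072 were then upward (56.5%), while with DESeq2 1179 of 2480 were (47.5%). With a filter of 5 CPM 500 of 1102 were upward (45.4%), and in cells thinned to 5000 UMIs 822 of 1863 (44.1%). SERPINA3 rose 53.9-fold to 23.96 ± 3.77 CPM, SLITRK6 46.3-fold to 22.0 ± 3.10 CPM, and S100P, a calcium-binding protein gene, 23.4-fold to 55.8 ± 16.5 CPM. PNPLA4 rose 22.2-fold, and MGP, the matrix Gla protein gene, rose 15.4-fold to 28.1 ± 4.68 CPM. The falls were led by TNFRSF11B, which encodes osteoprotegerin, from 40.0 ± 10.4 to 0.963 ± 0.0956 CPM. STC1 fell 12.1-fold, TDRD1 10.7-fold, MALRD1 10.1-fold and SFN, the 14-3-3 sigma gene, 8.88-fold. BAG3, a co-chaperone gene, fell from 182 ± 1.02 to 17.7 ± 0.0202 CPM. RHOBTB3 fell from 1600 ± 152 to 158 ± 4.87 CPM, and CA12, a carbonic anhydrase gene, from 183 ± 0.939 to 18.3 ± 0.184 CPM. GREB1, an oestrogen-induced gene, rose 1.28-fold, with an edgeR adjusted p of 4.0e-04.

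Cholesterol synthesis genes fell together in MCF7M1: all 24 tested members fell, and all 24 when adjusted over the list alone. MVD went from 34.1 ± 3.59 to 10.2 ± 0.775 CPM, LSS from 22.9 ± 0.413 to 7.99 ± 0.881 CPM, and INSIG1, a regulator of sterol sensing, from 36.9 ± 2.23 to 15.3 ± 1.16 CPM. Camera gave the list an adjusted p of 2.9e-07, and adjusted p = 0.669 with an estimated correlation. S phase genes also fell, 33 of 42 members (33 adjusted over the list alone) against 1 that rose. CLSPN, CDC6 and CCNE2, all part of DNA replication control, fell 2.70-fold, 2.52-fold and 2.44-fold. For this list camera's adjusted p was 5.5e-06, and adjusted p = 0.722 with an estimated correlation. Of 52 G2/M genes, 27 rose and 11 fell (28 and 11 adjusted over the list alone), with an adjusted p of 0.179.

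Immediate early and heat shock genes, which respond to cell handling, fell in 19 of 24 cases (19 adjusted over the list alone). NR4A1 fell from 60.9 ± 0.722 to 7.85 ± 2.78 CPM, and JUN from 186 ± 20.9 to 59.2 ± 3.42 CPM. The adjusted p of these genes was 0.00162, and adjusted p = 0.683 with an estimated correlation. Respiratory chain genes fell in 27 of 43 cases (29 adjusted over the list alone) and rose in 4, led by NDUFB8, NDUFS2 and COX6B1. NDUFB8, a complex I subunit gene, went from 156 ± 8.35 to 51.1 ± 1.28 CPM. Camera gave an adjusted p of 0.00173, and adjusted p = 0.735 with an estimated correlation.

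MAPK output genes, whose transcripts follow ERK activity, rose in 12 of 18 cases (12 adjusted over the list alone) and fell in 4. SPRED1 rose from 0.211 ± 0.0430 to 2.09 ± 0.0422 CPM. ETV5 and SPRY4 rose 17.0-fold and 25.9-fold from 0.0368 and 0.0207 CPM to 0.615 and 0.535 CPM. Their MCF7 levels rest on few UMIs, so the sizes of these folds are uncertain. Camera's adjusted p was 0.0172, and adjusted p = 0.669 with an estimated correlation. NRF2 target genes, which respond to oxidative stress, rose in 17 of 23 cases (17 adjusted over the list alone). SLC7A11, the cystine transporter gene, went from 8.39 ± 1.97 to 84.6 ± 10.2 CPM, and AKR1C1 from 1.93 ± 1.22 to 13.1 ± 5.65 CPM. For this list camera's adjusted p was 0.0468, and adjusted p = 0.776 with an estimated correlation. That call was lost with library sizes alone (adjusted p = 0.0562), without MCF7 replicate 1 (adjusted p = 0.0917), without MCF7M1 replicate 2 (adjusted p = 0.0635), without MCF7TR replicate 1 (adjusted p = 0.0684) and without MCF7TR replicate 2 (adjusted p = 0.0671).

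The other 22 lists did not pass in MCF7M1. Oestrogen-induced genes went both ways, with 18 of 40 higher and 16 lower (18 and 16 adjusted over the list alone) and an adjusted p of 0.557. In that list ELOVL2 fell 13.5-fold and KCNK5 7.94-fold, beside the rise of AREG. Luminal epithelial markers fell in 13 of 20 cases (13 adjusted over the list alone) and rose in 3, with an adjusted p of 0.0626. KRT18, a luminal keratin gene, fell from 9219 ± 230 to 3583 ± 99.4 CPM, and AGR2 rose from 8.46 ± 1.18 to 57.5 ± 8.09 CPM. That list passed without MCF7 replicate 2 (adjusted p = 0.0467) and without MCF7M1 replicate 1 (adjusted p = 0.0295). Basal epithelial markers had 8 of 16 members higher and 4 lower (8 and 4 adjusted over the list alone), with an adjusted p of 0.311. Among them CAV1 and CAV2, the caveolin genes, rose 35.03-fold and 10.1-fold. Unfolded protein response genes had 13 of 30 members higher and 16 lower (13 and 16 adjusted over the list alone), with an adjusted p of 0.987. Their median was -0.23 on the log2 scale while their mean and the test were positive. CHAC1, PSAT1, SLC7A11 and ASNS led the rises, with PSAT1 at 75.4 ± 7.21 CPM against 6.84 ± 0.752 CPM.

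p53 targets rose in 15 of 27 cases and fell in 5 (15 and 5 adjusted over the list alone), with an adjusted p of 0.0952. Fatty acid synthesis genes fell in 11 of 17 cases and rose in 3 (11 and 3 adjusted over the list alone), with an adjusted p of 0.0626, and FASN went from 183 ± 0.230 to 85.6 ± 13.4 CPM. That list passed without MCF7M1 replicate 1 (adjusted p = 0.0416). The chromatin architecture list held insulator, cohesin, condensin and lamina genes and other chromatin genes such as EZH2 and BRD4. Its members fell in 24 of 40 cases and rose in 8 (24 and 8 adjusted over the list alone), with an adjusted p of 0.0510. LMNB1, the lamin B1 gene, went from 77.3 ± 2.26 to 46.3 ± 2.61 CPM. This list passed without MCF7 replicate 2 (adjusted p = 0.0360) and without MCF7M1 replicate 1 (adjusted p = 0.0295), and the G2/M list passed without MCF7 replicate 2 (adjusted p = 0.0413). Both MCF7M1 libraries, and no others, came from the newer Cell Ranger version. Mesenchymal markers rose in 5 of 14 cases and fell in 2, junction genes in 5 and 11 of 20, and receptor tyrosine kinases in 3 and 9 of 19 (the same numbers adjusted over each list alone), with adjusted p of 0.352, 0.139 and 0.311. Interferon-stimulated genes rose in 13 of 40 cases and fell in 11, and MHC class I genes in 4 and 9 of 17, with adjusted p of 0.805 and 0.375. Hypoxia and glycolysis genes rose in 10 of 28 cases and fell in 15, and drug transport and metabolism genes in 10 and 12 of 25, with adjusted p of 0.465 and 0.550. YAP and TGF-beta output, stem-like, NF-kB target and BCL2 family genes had adjusted p of 0.924, 0.682, 0.557 and 0.805, and fibroblast, leukocyte and endothelial markers 0.376, 0.179 and 0.991. The median, the mean and the test differed in sign in 7 of these lists: hypoxia and glycolysis, unfolded protein response, drug transport, stem-like, NF-kB target, BCL2 family and endothelial genes. None of the 23 list calls of the 3 comparisons held with an estimated correlation.

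The count of changed genes was 7296 when cells were thinned to 5000 UMIs, which left 14539 genes to test, and 1548 genes passed a test against a 2-fold change.

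**Figure D1:**
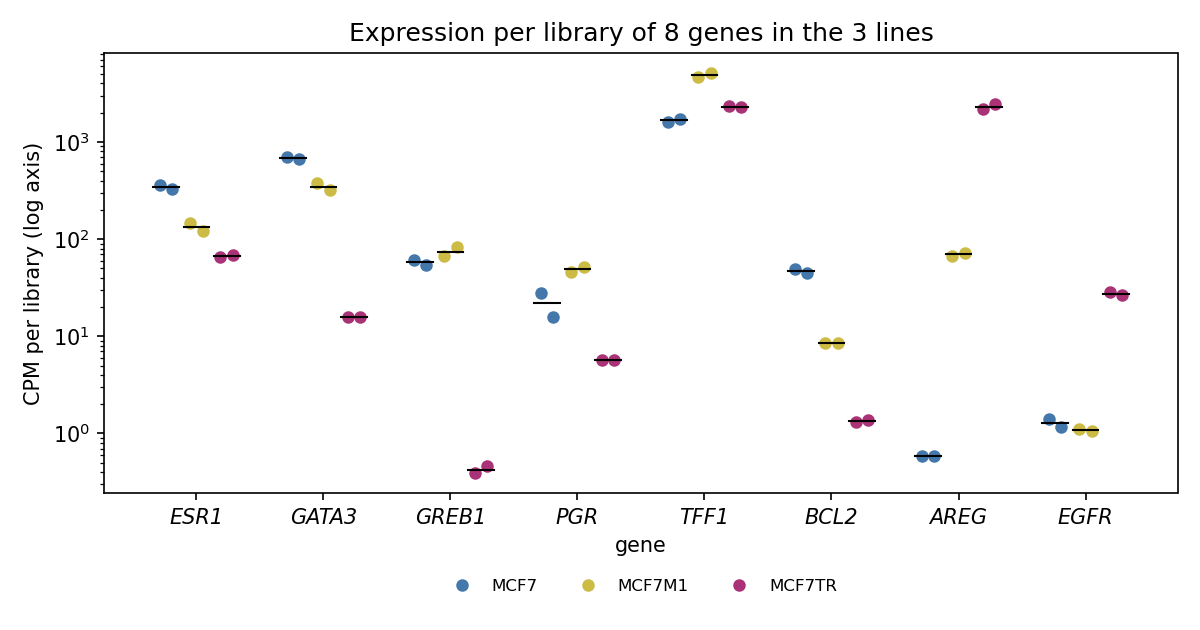
CPM of 8 genes (log axis) in each of the 6 libraries, coloured by line, with a black bar at the mean of the 2 libraries of a line. AREG lies at 0.593, 69.9 and 2318 CPM and ESR1 at 343, 134 and 67.3 CPM in MCF7, MCF7M1 and MCF7TR, and GREB1 is at 0.428 CPM in MCF7TR.

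MCF7TR was compared with MCF7 in the same way. MCF7TR expressed genes of which MCF7 had no UMI, and had no UMI of others that MCF7 expressed. LDHB, the lactate dehydrogenase B subunit gene, stood at 516 ± 17.5 CPM in MCF7TR with no UMI in either MCF7 library, at least 33343-fold higher. AREG reached 2318 ± 188 CPM, 3901-fold above MCF7. GREB1 fell from 57.9 ± 4.50 to 0.428 ± 0.0513 CPM and ESR1 from 343 ± 23.1 to 67.3 ± 1.80 CPM (SD, n = 2). BCL2 fell 34.6-fold to 1.36 ± 0.0484 CPM.

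The test called 14627 of 18789 genes (77.8%), 7159 upward and 7468 downward, and 6837 of them changed at least 2-fold, 2883 upward and 3954 downward. The majority at any size turned upward with DESeq2, at 6698 of 13313 genes (50.3%). CXCL8, which encodes the chemokine interleukin 8, stood at 126 ± 9.42 CPM, at least 8131-fold higher than in MCF7. SOX11, a transcription factor gene, and GUCY1A1, a guanylate cyclase subunit gene, were at least 1499-fold and 1454-fold higher. PEG10, an imprinted gene, reached 203 ± 15.01 CPM, 5638-fold higher. AASS, which acts in lysine breakdown, reached 187 ± 2.61 CPM, 5174-fold higher. Each of these 2 folds rests on 7 UMIs over both MCF7 libraries, so its size is uncertain. ETV4, an ETS factor gene, stood at 28.3 ± 0.0127 CPM against a single UMI in MCF7, a 5493-fold ratio of counts with an interval from 985 to 216990.

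In the other direction, RAMP1, a receptor activity-modifying protein gene, fell from 140 ± 17.2 CPM to no UMI, at least 9739-fold lower, and GSDMD, the gasdermin D gene, at least 3955-fold lower. ACOT4, WFDC2, FUOM and TENM3 were at least 3180-fold, 1960-fold, 1936-fold and 1823-fold lower, with no UMI in MCF7TR. PCSK1N, at 163 ± 9.09 CPM in MCF7, and TRGC1, at 236 ± 36.5 CPM, each had 1 UMI in MCF7TR, 33954-fold and 49140-fold lower with counting intervals from 6094 to 1341200 and from 8819 to 1941000. The TRGC1 value is uncertain, because its copy TRGC2 is nearly identical. PGR fell 3.82-fold and TFF1 rose 1.39-fold to 2315 ± 18.7 CPM. TFF1 no longer passed when tested against a 2-fold change, nor did PGR and GREB1 in MCF7M1 against MCF7, or ESR1 and TFF1 in MCF7TR against MCF7M1.

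Markers of luminal breast epithelium fell in 15 of 20 cases in MCF7TR and rose in 4 (15 and 4 adjusted over the list alone). GATA3, a transcription factor gene of luminal cells, fell from 688 ± 16.5 to 15.8 ± 0.211 CPM, and MUC1, a mucin gene, from 52.9 ± 0.935 to 0.958 ± 0.0289 CPM. TOX3 went the other way, from no UMI to 2.20 ± 0.0394 CPM. The adjusted p of these genes was 0.00990, and adjusted p = 0.669 with an estimated correlation. Interferon-stimulated genes fell in 28 of 40 cases and rose in 3 (28 and 3 adjusted over the list alone). IFITM3 went from 212 ± 19.7 to 0.315 ± 0.0821 CPM, BST2 from 26.6 ± 0.0319 to 0.0677 ± 0.0299 CPM, and IRF7, a regulator of the interferon response, from 8.47 ± 0.608 to 0.0291 ± 0.0147 CPM. Camera gave an adjusted p of 1.4e-04, and adjusted p = 0.669 with an estimated correlation.

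MAPK output genes rose in 16 of 18 cases and fell in 2 (16 and 2 adjusted over the list alone). SPRY4 reached 51.6 ± 1.97 CPM, DUSP6, an ERK phosphatase gene, went from 0.616 ± 0.104 to 35.9 ± 2.07 CPM, and ETV5 from 0.0368 to 20.5 CPM. Camera's adjusted p was 2.3e-04, and adjusted p = 0.669 with an estimated correlation. Hypoxia and glycolysis genes rose in 22 of 28 cases and fell in 5 (22 and 5 adjusted over the list alone). EGLN3 rose 7.66-fold and ADM 13.05-fold, while ENO2, the neuronal enolase gene, fell 11.5-fold. For this list camera's adjusted p was 0.00561, and adjusted p = 0.669 with an estimated correlation.

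S phase genes rose in 35 of 42 cases and fell in 3 (35 and 3 adjusted over the list alone), with CDC45, UHRF1 and RRM2 up 3.32-fold, 3.31-fold and 3.12-fold. The adjusted p of these genes was 3.0e-05, and adjusted p = 0.722 with an estimated correlation. G2/M genes rose in 39 of 52 cases and fell in 3 (40 and 3 adjusted over the list alone), with G2E3 at 158 ± 4.22 CPM against 28.2 ± 0.705 CPM and TACC3 at 94.4 ± 2.95 against 22.6 ± 2.07 CPM. Camera gave an adjusted p of 7.0e-05, and adjusted p = 0.735 with an estimated correlation.

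**Figure D2:**
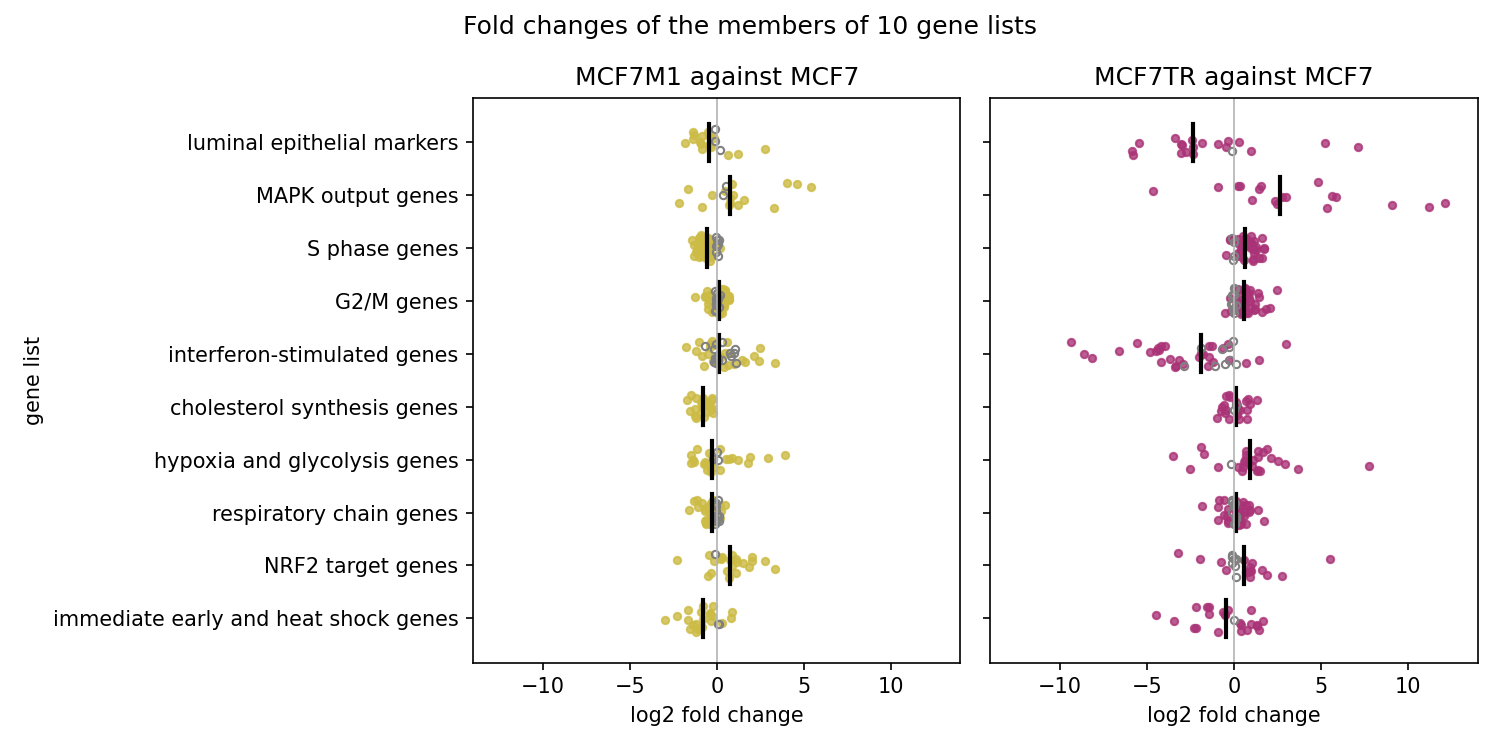
Log2 fold changes of the members of the 10 lists called in either comparison with MCF7, 1 point per gene, for MCF7M1 (left) and MCF7TR (right). Filled points passed the edgeR test, open points did not, black bars mark list medians, and genes without a UMI in 1 line are drawn at their bound. All 24 cholesterol synthesis genes lie below 0 in MCF7M1, and 16 of the 18 MAPK output genes lie above 0 and passed in MCF7TR.

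The remaining 22 lists did not pass in MCF7TR. Oestrogen-induced genes fell in 24 of 40 cases and rose in 13 (24 and 13 adjusted over the list alone), with an adjusted p of 0.106 that became 0.0360 without MCF7 replicate 2. CXCL12, a chemokine gene, and SUSD3 went from 13.7 ± 3.06 and 6.71 ± 0.375 CPM to no UMI. Mesenchymal markers rose in 9 of 14 cases and fell in 4 (9 and 4 adjusted over the list alone), with an adjusted p of 0.103. TPM2, a tropomyosin gene, went from 0.632 ± 0.129 to 621 ± 20.003 CPM, and FN1, the fibronectin gene, from 1.18 ± 0.0131 to 230 ± 1.92 CPM. Receptor tyrosine kinase genes went both ways, with 8 of 19 up and 8 down (8 and 8 adjusted over the list alone) and an adjusted p of 0.805. EGFR, the receptor of amphiregulin, rose from 1.28 ± 0.177 to 27.6 ± 1.63 CPM, and ERBB4 fell from 39.5 ± 1.35 to 0.0389 ± 0.0287 CPM.

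MHC class I genes fell in 11 of 17 cases and rose in 4 (11 and 4 adjusted over the list alone), with an adjusted p of 0.143, and TAPBP, the tapasin gene, fell from 78.3 ± 3.32 to 0.981 ± 0.103 CPM. Drug transport and metabolism genes fell in 16 of 25 cases and rose in 6 (16 and 6 adjusted over the list alone), with an adjusted p of 0.120. GSTM3 fell 145-fold from 798 ± 20.9 CPM, and ABCG2, an efflux transporter gene, 69.1-fold from 42.15 ± 2.61 CPM. YAP and TGF-beta output genes rose in 15 of 22 cases and fell in 6 (15 and 6 adjusted over the list alone), with an adjusted p of 0.0814. Of these, PMEPA1 rose 26.1-fold to 1224.5 ± 13.45 CPM. Stem-like and drug-tolerance genes rose in 12 of 23 cases and fell in 8 (12 and 8 adjusted over the list alone), with an adjusted p of 0.240. SOX2 stood at 5.69 ± 0.0940 CPM against a single UMI in MCF7, a 1104-fold ratio of counts with an interval from 198 to 43647, and CD44 fell 11.4-fold.

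BCL2 family genes rose in 10 of 16 cases and fell in 6 (10 and 6 adjusted over the list alone), with an adjusted p of 0.313, and BID, which encodes a pro-apoptotic member, rose from 34.9 ± 2.93 to 269 ± 9.55 CPM. Epithelial junction genes rose in 8 of 20 cases and fell in 9 (8 and 9 adjusted over the list alone), with an adjusted p of 0.927. NF-kB targets rose in 7 of 19 cases and fell in 8 (7 and 8 adjusted over the list alone), with an adjusted p of 0.785 despite the rise of CXCL8. Basal markers rose in 8 of 16 cases and fell in 7 (8 and 8 adjusted over the list alone), cholesterol synthesis genes rose in 12 of 24 and fell in 10, and respiratory chain genes rose in 23 of 43 and fell in 10, with adjusted p of 0.719, 0.686 and 0.179. Fatty acid synthesis, unfolded protein response, p53 target, NRF2 target, chromatin architecture and immediate early genes had adjusted p of 0.466, 0.433, 0.377, 0.128, 0.193 and 0.704. The median, the mean and the test differed in sign for junction genes, receptor tyrosine kinases and fatty acid synthesis genes. Of the markers of other cell types, 3 fibroblast, 3 leukocyte and 4 endothelial genes could be tested. Of these 2, 2 and 3 rose and 0, 0 and 1 fell (the same numbers adjusted over each list alone), with adjusted p of 0.377, 0.136 and 0.305, beside the rises of mesenchymal markers. CORO1A, a leukocyte marker, stood at 56.0 ± 1.40 CPM in MCF7TR against 1.31 ± 0.145 CPM in MCF7, while the leukocyte gene PTPRC had no UMI in any cell thinned to 5000 UMIs. The mitochondrial share of UMIs was 12.7 ± 0.729% in MCF7TR and 11.4 ± 0.977% in MCF7, and the ribosomal protein share was 20.7 ± 0.00400% and 22.8 ± 1.11%. The exact permutation p was 0.333 for both, the smallest it can be. When only genes of at least 5 CPM in 1 line were tested, 9194 of 10764 changed, and 5328 genes passed a test against a 2-fold change.

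MCF7TR was also set against MCF7M1. It differed from MCF7M1 more widely than MCF7M1 differed from MCF7, with 15090 of 18789 genes changed (80.3%), 7372 upward and 7718 downward. Of these, 7430 changed at least 2-fold, 3195 upward and 4235 downward. At any size, 6967 of 13673 changed genes were upward with DESeq2 (51.0%) and 6669 of 15043 with library sizes alone (44.3%). LDHB and CXCL8, without a UMI in MCF7M1, were at least 35384-fold and 8628-fold higher in MCF7TR, and GUCY1A1 was at least 1544-fold higher. AASS was 2956-fold higher, against 13 UMIs over both MCF7M1 libraries. SOX11 was at 23.2 ± 0.101 CPM against a single UMI, a 4774-fold difference with a counting interval from 856 to 188590. RAMP1, SUSD3, ACOT4 and GSDMD, at 67.1 ± 1.31, 46.3 ± 4.75, 36.4 ± 0.433 and 28.4 ± 2.94 CPM in MCF7M1, had no UMI in MCF7TR, at least 4664-fold, 3217-fold, 2530-fold and 1974-fold lower. PCSK1N fell from 86.5 ± 2.55 CPM to a single UMI, 18034-fold with a counting interval from 3236 to 712360. ESR1, PGR, GREB1, TFF1 and BCL2 were all lower, by 2.00-fold, 8.47-fold, 174-fold, 2.11-fold and 6.35-fold.

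Camera called 11 of 28 lists between MCF7TR and MCF7M1, 8 upward and 3 downward. Interferon-stimulated genes were lower in 36 of 40 cases (36 adjusted over the list alone), with an adjusted p of 3.0e-05 and adjusted p = 0.669 with an estimated correlation. Oestrogen-induced genes were lower in 28 of 40 cases (28 adjusted over the list alone), with an adjusted p of 0.00562 and adjusted p = 0.735 with an estimated correlation. HSPB8 fell 117-fold in that list. Luminal markers were lower in 14 of 20 cases (14 adjusted over the list alone), with an adjusted p of 0.0260 and adjusted p = 0.683 with an estimated correlation.

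S phase genes were higher in MCF7TR in 39 of 42 cases (40 adjusted over the list alone), with CDC6 at 42.2 ± 1.49 against 8.51 ± 0.283 CPM. The adjusted p was 2.3e-08, and adjusted p = 0.702 with an estimated correlation. G2/M genes were higher in 35 of 52 cases (36 adjusted over the list alone), with an adjusted p of 0.00170 and adjusted p = 0.776 with an estimated correlation. MAPK output genes were higher in 15 of 18 cases (15 adjusted over the list alone), with an adjusted p of 9.1e-04 and adjusted p = 0.669 with an estimated correlation. FOSL1, an AP-1 factor gene, rose from 0.301 ± 0.0234 to 10.5 ± 0.0358 CPM. Cholesterol synthesis genes were higher in 19 of 24 cases (19 adjusted over the list alone), with FDPS at 355 ± 20.4 against 83.0 ± 8.59 CPM. The adjusted p was 9.1e-04, and adjusted p = 0.722 with an estimated correlation.

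Respiratory chain genes were higher in 33 of 43 cases (33 adjusted over the list alone), with an adjusted p of 0.00154 and adjusted p = 0.735 with an estimated correlation. Hypoxia and glycolysis genes were higher in 20 of 28 cases (20 adjusted over the list alone), with an adjusted p of 0.0215 and adjusted p = 0.669 with an estimated correlation. PKM, the pyruvate kinase gene, stood at 1458 ± 57.4 CPM against 280 ± 14.4 CPM. Chromatin architecture genes were higher in 27 of 40 cases (27 adjusted over the list alone), with an adjusted p of 0.0128 and adjusted p = 0.722 with an estimated correlation. The condensin genes NCAPH and NCAPD2 rose 3.36-fold and 3.21-fold, and LMNB2, the lamin B2 gene, 3.52-fold. Mesenchymal markers were higher in 11 of 14 cases (11 adjusted over the list alone), with an adjusted p of 0.0390 and adjusted p = 0.669 with an estimated correlation. That call was lost without MCF7TR replicate 1 (adjusted p = 0.0684). Markers of other cell types moved the same way, with 2 of 3 fibroblast, 3 of 3 leukocyte and 3 of 4 endothelial markers higher (the same numbers adjusted over each list alone) and adjusted p of 0.273, 0.0796 and 0.297. YAP and TGF-beta output genes, at an adjusted p of 0.0789, passed only without MCF7M1 replicate 1 (adjusted p = 0.0496). The median, the mean and the test differed in sign only for receptor tyrosine kinases. When only genes of at least 5 CPM in 1 line were tested, 9235 of 10764 changed, and 5765 genes passed a test against a 2-fold change.

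The changes of both lines against MCF7 were then set side by side. Genes that rose in both numbered 2759, genes that fell in both 3218, and genes that changed in opposite directions 3715. Independent lists of these sizes would give 2208, 2423 and 4626. At a 2-fold change or more the numbers were 592, 804 and 450, against 236, 317 and 555. AREG rose in both lines, and ESR1, BCL2, TNFRSF11B, TDRD1 and MALRD1 fell in both, while PGR rose in MCF7M1 and fell in MCF7TR. In 20 simulations of unchanged groups against the same MCF7 libraries, no gene was called in both comparisons. That follows from their having no changed gene, so it does not measure how shared controls add to the overlap. The log2 fold changes correlated at 0.31 over genes, against 0.51 in the simulations, and 56.8% had the same sign, against 66.9%. Their covariance was 0.47, against 0.02 in the simulations, a difference of 0.46. Simulated fold changes shared nothing but the MCF7 libraries, so their higher correlation does not mean that the real changes were shared less. With another MCF7 library in each comparison, a split added after the data were seen, 1280 genes changed at least 2-fold the same way in either split, against 529 and 510 of independent lists, and 446 and 426 changed in opposite directions. Each comparison then rests on 1 MCF7 library, and both may stem from 1 culture, so part of the excess may come from the shared controls.

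Shares of cells with a UMI depend on the mean level, so alone they do not show whether a difference lay in all cells or in some. At 5000 UMIs per cell, ESR1 was detected in 76.9 ± 0.779% of MCF7 cells, 45.2 ± 3.71% of MCF7M1 cells and 26.8 ± 1.62% of MCF7TR cells (SD, n = 2). GREB1 was detected in 25.03 ± 0.461%, 29.3 ± 2.53% and 0.220 ± 0.137%, PGR in 8.37 ± 2.02%, 18.2 ± 0.424% and 2.78 ± 0.541%, and BCL2 in 20.8 ± 0.589%, 4.001 ± 0.0970% and 0.675 ± 0.198% of cells in the same order. MKI67, a proliferation marker, was detected in 24.2 ± 0.136%, 17.5 ± 0.762% and 40.3 ± 2.57%, with means of 0.548, 0.333 and 0.695 UMIs per cell and Fano factors of 3.32, 2.82 and 1.80. TFF1 was detected in 77.1 ± 5.67%, 97.7 ± 0.200% and 78.9 ± 0.876%. Cells of equal expression would give 42.2%, 28.3% and 50.1% for MKI67 and at least 99.97% for TFF1. Both genes thus varied between cells beyond counting error in each line. For ESR1 equal cells would give 83.3%, 50.1% and 30.2%, closer to the shares found but above them in each line. Its Fano factors were 1.523, 1.365 and 1.329, so ESR1 also varied between cells beyond counting error. Barcodes that failed the cell filter were included. Without thinning, the shares were 88.7%, 66.2% and 60.9% for ESR1, 62.5%, 53.5% and 1.43% for GREB1, 26.2%, 35.3% and 15.4% for PGR, 60.03%, 10.4% and 4.42% for BCL2, 39.5%, 25.5% and 61.8% for MKI67, and 81.2%, 92.1% and 79.6% for TFF1. Among markers of other cell types, the endothelial gene CDH5 and the leukocyte gene PTPRC had no UMI in 5180, 7002 and 4640 thinned cells, while COL1A1, a fibroblast marker, had one in 2.65 ± 0.205%, 1.36 ± 0.228% and 5.30 ± 0.705% of them. LYZ, a myeloid gene, had one in 0.109 ± 0.0380% of MCF7TR cells. At 5000 UMIs the exact permutation p was 0.333 for each pair of lines for ESR1, PGR, GREB1, BCL2 and MKI67, and for TFF1 except in MCF7TR against MCF7, where it was 1.0. The other shares were not tested.

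Phase calls were computed from the S phase and G2/M lists, so they are not evidence independent of the list results. S phase calls made up 31.8 ± 0.271% of MCF7 cells, 18.3 ± 2.00% of MCF7M1 cells and 61.8 ± 0.378% of MCF7TR cells. G2/M calls made up 14.4 ± 0.899%, 15.4 ± 0.0180% and 26.0 ± 1.59%, and G1 calls 53.8 ± 0.628%, 66.3 ± 1.99% and 12.2 ± 1.97%. The exact permutation p was 0.333 for each pair of lines and each phase. Scored within each line, an alternative chosen after the data were seen, S phase calls made up 30.4%, 29.1% and 51.0% of cells. The gap between MCF7 and MCF7M1 was thus much smaller than with the lines scored together. Scoring each line against its own cells can absorb a difference shared by a whole line. The smaller gap therefore cannot decide whether MCF7M1 held fewer S phase cells. Phase calls read free RNA in the droplets too, whose level in each library was not measured.

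**Figure D3:**
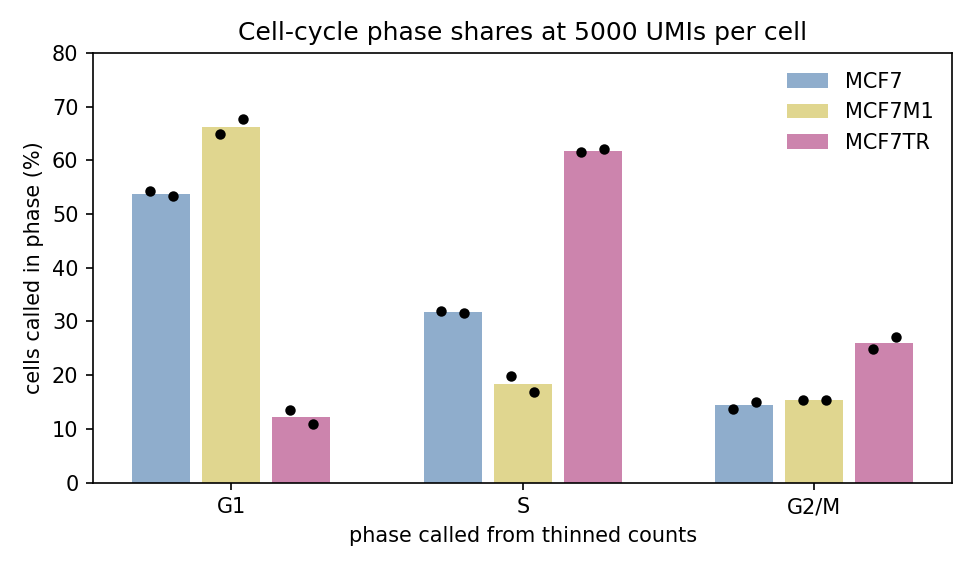
Percent of cells called in G1, S and G2/M at 5000 UMIs per cell, by line. Bars start at 0 and show the mean of 2 libraries, points the libraries. S phase calls make up 61.8% of MCF7TR cells, 31.8% of MCF7 cells and 18.3% of MCF7M1 cells.

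The median Fano factor over genes was 1.07 ± 0.0201 in MCF7, 1.05 ± 0.00360 in MCF7M1 and 1.07 ± 0.00760 in MCF7TR, where counting error alone gives about 1. The exact permutation p was 0.667 for MCF7M1 against MCF7, 1.0 for MCF7TR against MCF7 and 0.333 for MCF7TR against MCF7M1. Both MCF7TR libraries lay above both MCF7M1 libraries at this depth, but the lines overlapped at 2500 and 10000 UMIs. A test of 2 against 2 libraries cannot show that lines do not differ. The lines themselves hardly mixed. Among the 30 nearest neighbours of a cell, cells of another line made up 1.44 ± 0.479% for MCF7, 0.882 ± 0.164% for MCF7M1 and 0.0140 ± 0.00800% for MCF7TR, where cell numbers alone would give 66.7%. Cells of the other library of the same line made up 45.3 ± 2.30%, 45.7 ± 0.789% and 48.6 ± 0.227%. Clustering gave 7 clusters, in each of which at least 98.25% of the cells came from a single line.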

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

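Library sizes alone, the estimated correlation on filtered cells, phases scored within each line and separate MCF7 libraries for the overlap were added after the data were seen. All other alternatives were set earlier. Of 2165 results under an alternative, 2014 were labelled the same, 907 of them single genes that were mostly chosen for large changes. None of the 912 single-gene and 1008 single-list results reversed. Counts were labelled by size and per-cell values only as the same or moved, so a reversal could not show there. The majority direction of changed genes did turn, with library sizes alone in MCF7M1 against MCF7 and with DESeq2 in both MCF7TR comparisons. The cause of a move was not tested unless the construction of the alternative shows it.

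Genes changed in MCF7M1 against MCF7 numbered 7296 of 14539 tested in cells thinned to 5000 UMIs, of which 6993 were shared. A test against a 2-fold change (glmTreat) left 1548, 5328 and 5765 genes in MCF7M1 against MCF7, MCF7TR against MCF7 and MCF7TR against MCF7M1, as its stricter null requires. With a filter of 5 CPM, 9194 and 9235 of 10764 genes changed in the MCF7TR comparisons. At least 2-fold changes then numbered 1102, 2799 and 3045. In MCF7M1 against MCF7 they numbered 1863 in thinned cells and 1548 under glmTreat. DESeq2 gave 9761, 13313 and 13673 changed genes. Leaving out 1 library gave 10717 to 11551, 13646 to 14942 and 14141 to 15475 changed genes. Of 912 single-gene results, 5 were lost, all under glmTreat.

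Gene lists called fell from 6, 6 and 11 to 0, 0 and 0 with an estimated correlation, and to 0, 0 and 0 with filtered cells as well. As the MAPK output genes show, these losses cannot be put down to the correlation alone. Leaving out 1 library gave 5 to 9, 6 to 7 and 10 to 12 called lists, with 5 calls lost and 8 gained.

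Genes changed at least 2-fold in both lines numbered 592 upward, 804 downward and 450 opposite, against 2759, 3218 and 3715 at any size, by construction of the threshold. With another MCF7 library in each comparison they numbered 2368 or 2411, 2952 or 2870 and 3340 or 3259 at any size. The replicate numbers did not pair across lines, with correlations of 0.03, 0.08 and -0.06. Blocking on them gave 11725, 14549 and 15005 changed genes.

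S phase calls were 33.5%, 21.8% and 62.3% in MCF7, MCF7M1 and MCF7TR at 2500 UMIs, 33.3% in MCF7 at 10000 UMIs, and 30.4%, 29.1% and 51.0% scored within each line. G2/M calls were 15.04% in MCF7M1 and 22.1% in MCF7TR at 2500 UMIs, 15.4%, 16.5% and 28.4% at 10000 UMIs, and 19.6% in MCF7M1 and 28.0% in MCF7TR within each line. Shares of cells with a UMI moved with depth in 35 of 36 cases, by construction.

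In filtered cells the mitochondrial share was 9.69%, 9.82% and 10.5%, lower by construction of the filter, and the ribosomal share 24.1% in MCF7M1 and 21.5% in MCF7TR. The median Fano factor of MCF7M1 was 1.064 at 2500 UMIs and 1.059 at 10000 UMIs, where that of MCF7TR was 1.0634 and 1.0614. Neighbours of another line made up 2.21%, 1.82% and 0.258% at 2500 UMIs, 0.445% for MCF7M1 and 0.0018% for MCF7TR at 10000 UMIs, 0.716% for MCF7M1 with 15 neighbours, and 1.11% for MCF7M1 and 0.0248% for MCF7TR with 60. Clusters numbered 4 and 11 at resolutions of 0.25 and 1.0.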

Other observations

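The tests on depth in MCF7TR, on low-quality barcodes and on separate MCF7 libraries were chosen after the results were seen, and so were the genes named in this and the next paragraph. The list of unfolded protein response genes was not called in MCF7M1 against MCF7, with 13 of 30 members up and 16 down and an adjusted p of 0.987, and single members went apart. HSPA5, a chaperone gene, fell from 576 ± 71.6 to 204 ± 9.69 CPM, SDF2L1 from 269 ± 26.5 to 42.9 ± 3.40 CPM, and MANF from 266 ± 39.0 to 67.0 ± 7.13 CPM (SD, n = 2). ATF4, a transcription factor gene, rose from 84.6 ± 1.80 to 177 ± 9.26 CPM, DDIT3 from 24.995 ± 1.02 to 69.5 ± 6.85 CPM, and PHGDH, an enzyme of serine synthesis, from 31.6 ± 5.91 to 241 ± 22.2 CPM. No division of this list was tested.

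In the hypoxia and glycolysis list, where 22 of 28 members rose and 5 fell in MCF7TR against MCF7, LDHA rose from 371 ± 14.1 to 1057 ± 51.4 CPM and GAPDH from 2383 ± 223 to 6282 ± 266 CPM. ENO2, SLC2A3 and SLC2A1, the latter glucose transporter genes, fell, with log2 fold changes of -3.52, -2.50 and -0.93, and PFKFB4 did not pass, at -0.17. GPX4, which detoxifies lipid peroxides, stood at 1014 ± 11.3 against 183 ± 3.57 CPM. The keratin gene KRT8 fell from 6381 ± 148 in MCF7 to 2561 ± 2.22 in MCF7M1 and 1199 ± 37.6 CPM in MCF7TR. CTCF, the insulator protein gene, stood at 88.5 ± 0.665, 85.0 ± 0.0850 and 96.6 ± 1.70 CPM.

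In MCF7TR, 19 genes of at least 20 CPM in MCF7, among them RAMP1, GSDMD and ERBB4, lay below 0.1 CPM, and 17 genes of at least 20 CPM in MCF7TR, among them LDHB and CXCL8, lay below 0.1 CPM in MCF7. The MCF7TR libraries held more UMIs than those of MCF7, 110035737 and 105019248 against 100542384 and 94994779, which speaks against low depth. At their MCF7 level each of the 19 would have had at least 4924 UMIs, a figure largely set by their choice at 20 CPM or more and by those totals. Complete loss of a chromosome segment would silence neighbours too. Of 38 flanking genes, 3 (7.89%) were silent, and the median ratio of the 38 to their MCF7 level was 0.77. The share of silent genes among all expressed genes was not computed. Most neighbours were still expressed, which argues against complete loss of segments that reach them. Both neighbours of RAMP1 (0.369 and 0.232), PCSK1N (0.498 and 0.459) and ZNF22 (0.0 and 0.294) lay below that median. The same held for TENM3 (0.001 and 0.682), LINC00472 (0.192 and 0.642), TDRD1 (0.517 and 0.076) and PLAAT3 (0.0 and 0.615). Loss around all these genes stays open. Of the 19 genes, 18 were lower in MCF7M1 than in MCF7, and ZNF22 was not. All 19 were chosen for at least 20 CPM in the same MCF7 libraries, which favours lower values in MCF7M1. The share of lower genes among all genes at that MCF7 level was not computed. The count therefore cannot show whether MCF7M1 shares the loss of these genes. Silencing, small deletions and differences between the stocks of the lines, whose descent the labels do not give, all stay open.

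Fold changes were shared along chromosomes. At a distance of 20 genes they correlated at 0.0706 in MCF7M1 and 0.0788 in MCF7TR once GC content and transcript length were removed, which copy-number differences would give. That removal kept 64.8% of the correlation in MCF7M1, so GC content and length may explain part of it there, and 99.1% in MCF7TR, where they do not explain it. Domains of chromatin would give the same pattern, and these counts cannot separate them from copy number.

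The difference between MCF7M1 and MCF7 could come from the Cell Ranger version, which differed between them. Of the genes changed at least 2-fold in MCF7M1, 45.82% changed the same way in MCF7TR, whose version was that of MCF7, against 18.2% of independent lists. With another MCF7 library in each comparison the count was at least 2.42 times that of independent lists and above that of opposite changes, which argues against the version as the whole cause, while its part in the difference stays open. After the cell filter 2999 genes changed at least 2-fold, against 3047 before, which speaks against low-quality barcodes. Barcodes with few genes and few mitochondrial UMIs made up 18.7% and 11.1% of the MCF7M1 libraries and at most 3.19% of the others.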
